A study of Escherichia coli Nissle 1917 with 96 samples.

How the data were processed

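RNA was sequenced from 12 strains of Escherichia coli Nissle 1917 grown with or without 1 mM IPTG for 5 h. Per the labels, total RNA was extracted, libraries were pooled over the lanes of an Illumina NovaSeq flow cell, and replicates were biological. The authors deposited a single table of FPKM values (fragments per kilobase of transcript scaled to the mapped fragments of the library) for all 96 libraries. Trimmomatic and featureCounts are named in the submitters' processing notes. The aligner, the genome build and the denominator of the FPKM values were not given in the sources used here. Groups and replicate numbers came from the sample titles. The labels state that 4 libraries did not pass a check of mapped reads and were left out of the comparisons.

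The table had 4778 host genes besides 19 circuit transcripts. Most host genes carry an ECOLIN locus tag that the files do not pair with a name, and 591 carry a gene symbol. Of those, 560 matched the gene table of E. coli assembly ASM584v2, which matched 0 tags and gave names and gene lengths. Genes with an FPKM of at least 5 in at least 3 libraries were kept, which left 2565 host genes, 425 of them with a symbol. Named genes and lists therefore cover a small part of the genome.

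FPKM values are not counts, so tests were run on log2(FPKM + 1), on which every log2 change is given. This scale understates the change of genes with low values. One linear model with a mean for each of the 24 groups was fitted with limma 3.58.1 in R 4.3.3, with trended empirical Bayes variances and 68 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method within each of 44 comparisons. A gene was called changed at an adjusted p under 0.05 and an absolute log2 change of at least 1. The comparisons were the IPTG response of each strain, SensorArray against WT at each IPTG level, each gate against SensorArray at each level, and the difference between the IPTG response of each gate and that of SensorArray. Comparisons with SensorArray share its libraries, so genes changed in several gates were set beside 100 simulations of unchanged gates, independent lists and a split of the controls. Lists called in several gates, and genes changed in most gates without IPTG, were set beside 100 draws of whole-library residuals, a check added after the values were seen. Groups, the tests of host genes and lists, thresholds, gene lists, the naming rule and all but 1 of the alternative settings were chosen before the data were examined. The tests of circuit transcripts and a few named genes were chosen after.

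Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 38 lists, 26 had at least 3 tested members. The bet regulon, MarA efflux, osmotic stress, colanic acid and capsule, and microcin and colibactin lists had 0 tested members and gave no result. Genes were named by a rule. The lac genes that changed and the circuit transcripts were always named. For the IPTG responses of WT and SensorArray and for SensorArray against WT, up to 10 genes per direction were taken by size of change among changed genes whose libraries did not overlap, and for each gate up to 3 per direction. The genes changed in most gates with IPTG and 2 to 4 changed members of each list described were added. Genes with symbols came first, and at most 2 tags per direction were named. putA where the rule does not reach it, and the 3 transcripts found in WT and few other libraries, were named after their values were seen.

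Circuit transcripts were planned for the same model, but strains that lack a part add libraries with no spread, which made its p-values far too small. They were tested instead within each strain by two-sided exact permutation tests, a choice made after the data were examined. With 4 against 4 or 3 against 4 libraries the smallest p is 0.0286, and with 3 against 3 it is 0.1. Of the host genes tested, 0 were at 0 in every library of a group.

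With the assembly's gene lengths, depth was recovered from steps between low FPKM values in a library. Of these 15558, 86.6% were whole numbers of reads within 0.02, against 4% by chance. Libraries that passed held 3.01 to 158 M counted reads, 1 of them under 4 M. The libraries left out held 0.117 M (PhlF no-IPTG 3), 1.66 M (PhlF IPTG 2), 2.11 M (AmtR IPTG 2) and 19.2 M (BM3R1 no-IPTG 4), so depth does not set the last apart. Low genes in shallow libraries are measured with the largest counting error. Over 487 genes, all 144 replicate pairs differed by more than counting noise (lowest chi-square per degree of freedom 1.39, median 8.1), and no pair was treated as 1 library.

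Alternatives were a pseudocount of 5, no filter, median-ratio scaling (factors from 0.732 to 1.5), all 96 libraries, leaving out each library in turn, fitting the compared groups alone, and replicate number as a block. Leaving out 7 libraries with reads of transcripts found in WT, which left 85, was added after the data were seen. The procedure was tested on simulated data for SensorArray against WT with IPTG over 2565 genes. It recovered 98% of genes changed by 1.5 on the log2 scale and 100% of those changed by 2, with 1 false call. These rates apply to simulated noise and not to the real libraries. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.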

Results

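Transcript levels were measured by RNA sequencing in Escherichia coli Nissle 1917, a probiotic gut strain, and in 11 engineered derivatives. According to the title of the series, the work addressed the burden that genetic circuits place on a Nissle treatment for phenylketonuria, an inherited failure to break down phenylalanine. The wild type (WT) carried no circuit, SensorArray carried a set of sensor regulators, and each of 10 gate strains carried a NOT gate named for its repressor (PsrA, HlyIIR, BM3R1, AmtR, QacR, LitR, AmeR, IcaR, BetI or PhlF). In a NOT gate the inducer switches on a repressor, which switches off an output, here YFP. Each strain was grown for 5 h in minimal medium without IPTG or with 1 mM IPTG, an inducer of the lac repressor. There were 4 biological replicates in each of 24 groups, 96 libraries in all. Of these, the 92 that passed were compared. PhlF had 3 libraries at each IPTG level, BM3R1 had 3 without IPTG, AmtR had 3 with IPTG, and every other group had 4. Counted reads had a median of 28.1 M in the libraries that passed. Libraries are named here by strain, IPTG state and replicate number, as in SensorArray no-IPTG 4.

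The repressor and YFP transcripts were compared first, because they show whether each gate switched. IPTG raised the repressor and lowered YFP in 9 of 10 gate strains (two-sided exact permutation test within strain, p = 0.0286, the smallest these group sizes allow, adjusted p = 0.0317 over 20 tests). HlyIIR rose 149-fold, from 49.7 ± 16.6 to 7400 ± 4380 FPKM (SD, n = 4). LitR rose 93.4-fold to 4500 ± 1850 FPKM and AmeRS 87.6-fold to 3020 ± 136 FPKM. The smallest increases were 2.96-fold for AmtR, from 43.2 ± 5.72 (n = 4) to 128 ± 8.08 FPKM (n = 3), and 4.66-fold for IcaR, from 24 ± 20.1 to 112 ± 27.2 FPKM. Without IcaR no-IPTG 1 (53.9 FPKM) the first mean was 14 ± 2.35 FPKM (n = 3) and the rise 7.99-fold, the only fold of a repressor or YFP that a single library moved by over 1.5 times. BM3R1 rose 48.2-fold, PsrA 15.2-fold, QacR 13.9-fold and BetI 12-fold. YFP fell 122-fold in the PsrA strain, from 2210 ± 150 to 18.2 ± 5.59 FPKM, and 104-fold in the AmeR strain, from 327 ± 20.1 to 3.14 ± 0.75 FPKM. In the QacR strain it fell 1.77-fold, from 828 ± 88.6 to 467 ± 40 FPKM. The other folds for YFP were 83.2 with HlyIIR, 51.6 with AmtR, 39.8 with IcaR, 27.2 with BM3R1, 11.9 with LitR and 9.28 with BetI. In the PhlF strain the means were 41.3 ± 17.7 and 676 ± 130 FPKM for PhlF and 1520 ± 245 and 7.64 ± 1.27 FPKM for YFP (n = 3 and 3), and the exact permutation test could not go below its p of 0.1. YFP was listed at 0 in WT and SensorArray. For the sensor regulators the exact test could hardly be passed after adjustment. To reach an adjusted p of 0.05, 79 of 138 tests of a gate against SensorArray had to lie at the smallest p, where 37 did (adjusted p = 0.107), and 44 of 77 tests of an IPTG response, where 10 did (adjusted p = 0.22). This leaves open whether they differed. Among the 37 with IPTG were TetR in AmeR (log2 change 1.66, SE 0.14, exact p = 0.0286), at 412 ± 62.2 against 129 ± 16.7 FPKM in SensorArray (n = 4), and LacI there (0.96, SE 0.11). TetR in HlyIIR (1.60, SE 0.22, exact p = 0.0286) stood at 402 ± 117 FPKM. Without IPTG the difference in HlyIIR was 2.37 (SE 0.57) for TetR and 2.01 (SE 0.62) for LacI. In AmeR it was 2.26 (SE 0.57) and 2.03 (SE 0.62). SensorArray no-IPTG 2 and 3 held transcripts otherwise seen in WT. Their lower TetR (21% and 33.6% of the other 2) and LacI (17.7% and 29.8%) enlarged these differences. The IcaR strain carried CymR-GV at 8680 ± 377 FPKM without IPTG and 8980 ± 246 with it, and CymR-AM was listed at 0 there.

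**Figure D1:**
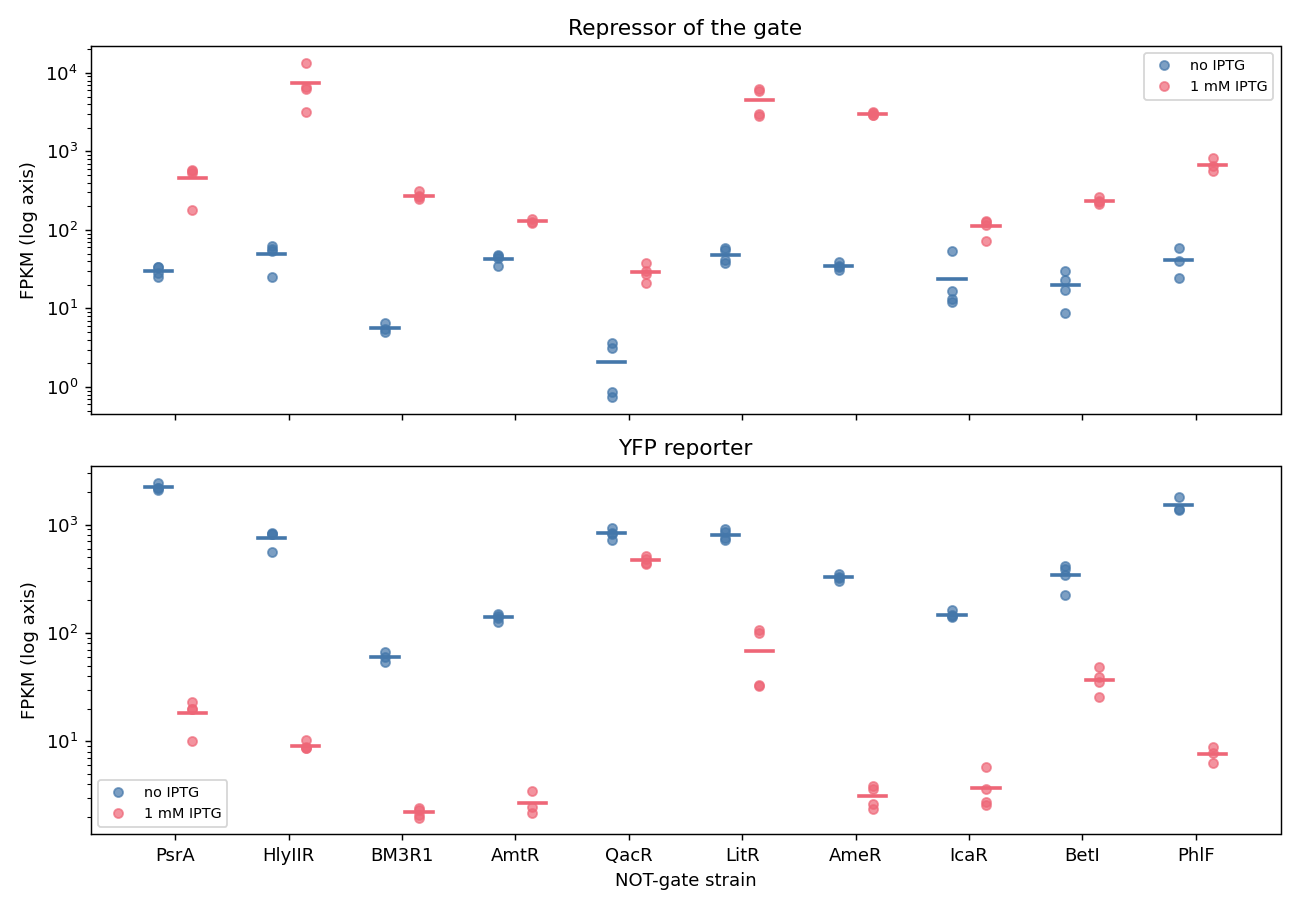
FPKM of the strain's own repressor (first panel) and of YFP (second panel) per library on log axes, by gate strain, in blue without IPTG and in red with 1 mM IPTG, with a line at each mean. Repressor means rise by between 2.96-fold (AmtR) and 149-fold (HlyIIR), and YFP means fall by between 1.77-fold (QacR) and 198-fold (PhlF).

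Some libraries stood apart from their group. The transcripts ECOLIN_22000, ECOLIN_22005 and ECOLIN_22010, chosen after their values were seen, summed to 6.49 ± 1.07 FPKM in WT (SD, n = 8) and to at most 0.473 FPKM in 77 engineered libraries. In 7 other engineered libraries the sum was above 1 FPKM. It was 6.15 in BetI no-IPTG 1, 3.15 in SensorArray no-IPTG 2, 2.26 in PhlF no-IPTG 1, 2.14 in PsrA IPTG 2, 1.82 in SensorArray no-IPTG 3, 1.52 in BetI IPTG 1 and 1.08 in BetI no-IPTG 2. The same SensorArray libraries had lacZ at 55 and 46.1 FPKM, against 4.27 and 2.83 FPKM in SensorArray no-IPTG 1 and 4. As SensorArray is the control of every gate comparison, results for named genes and counts are also given without these 7 libraries where that ended a call or moved a value by over 1.5 times, a setting added after the data were seen. Of 104 calls of gene lists, 28 were lost without them and 45 others gained. One further library, HlyIIR no-IPTG 4, had the HlyIIR transcript at 25.4 FPKM, where the other 3 libraries lay between 53.7 and 61.9 FPKM.

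**Figure D2:**
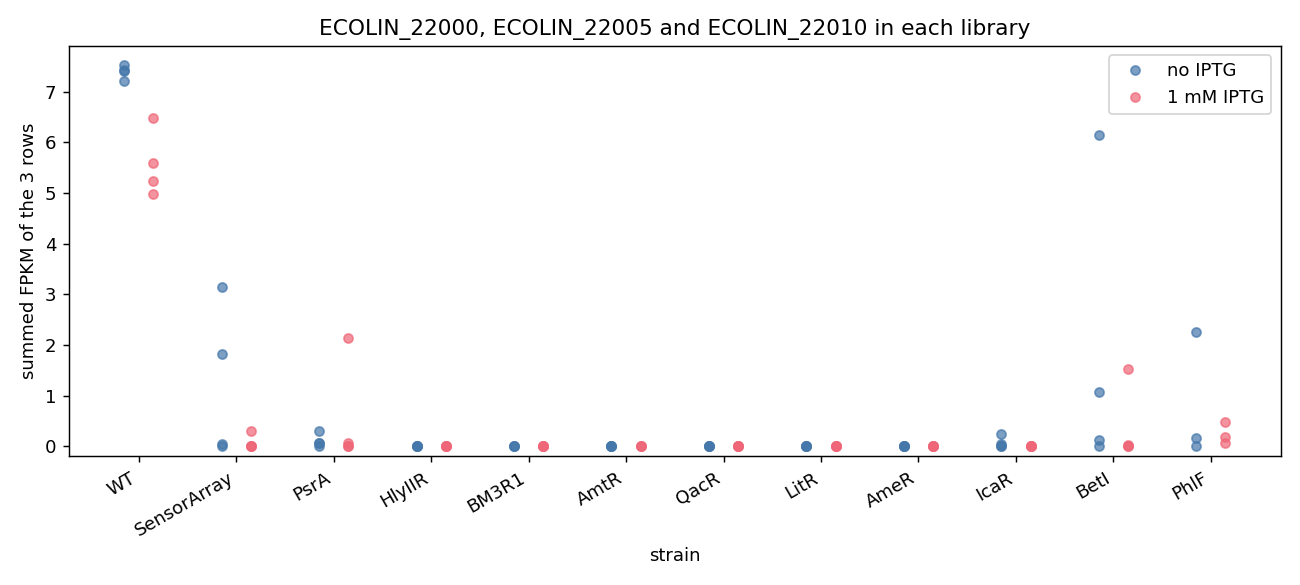
Summed FPKM of ECOLIN_22000, ECOLIN_22005 and ECOLIN_22010 in each library, by strain. WT libraries average 6.49 FPKM, 7 engineered libraries lie between 1.08 and 6.15 FPKM, and the other 77 engineered libraries lie at or below 0.473 FPKM.

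The question in WT, which holds no circuit, was what IPTG alone changes. lacZ, the gene of beta-galactosidase, rose by 2.50 on the log2 scale (SE 0.47, limma adjusted p = 0.00041), from 77.3 ± 6.03 to 440 ± 19.2 FPKM (n = 4). lacY, the lactose permease, rose by 2.38 (SE 0.46) from 32.5 ± 2.35 to 173 ± 11.4 FPKM. All 3 measured lac genes rose (3 adjusted over the list alone, list adjusted p = 1.1e-12), and the call held with an estimated correlation. The tag ECOLIN_23100 rose by 5.51 (SE 0.19), from 14.6 ± 1.31 to 705 ± 24.1 FPKM. ECOLIN_00305 (log2 change -1.74) and ECOLIN_00310 (-1.58) fell. Of 3 measured histidine synthesis genes, hisG, which catalyses the opening step, fell by 1.54 (SE 0.38, limma adjusted p = 0.0082) and hisD fell by 1.30 (SE 0.40, limma adjusted p = 0.048), 2 adjusted over the list alone (list adjusted p = 0.018, adjusted p = 0.8 with an estimated correlation). aceK, which modifies isocitrate dehydrogenase, fell by 1.27 (SE 0.33). None of 23 ribosomal protein genes passed the test, although their list was called lower with a median log2 change of -0.62 (adjusted p = 0.00071, adjusted p = 0.8 with an estimated correlation). In all, 22 genes changed in limma, 4 higher and 18 lower, against 4 higher and 5 lower after median-ratio scaling. Scaling ended the calls of hisG (-1.30), hisD (-1.08) and aceK (-1.03). The hisD call ended without any 1 of the 8 libraries, that of hisG without WT IPTG 4 (-1.36) and that of aceK without WT no-IPTG 4 (-0.68). The count fell to 13 without WT no-IPTG 4 and to 13 without WT IPTG 4.

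In SensorArray, IPTG again raised lacZ, by 4.15 on the log2 scale (SE 0.47, limma adjusted p = 1.9e-10), from 27.1 ± 27.4 to 272 ± 48.1 FPKM (n = 4). The value was 5.91 without the 7 libraries. lacY rose by 3.74 and lacA by 3.23 (4.92 without those libraries), so that all 3 lac genes rose (3 adjusted over the list alone). The arabinose transporter genes araG and araH fell. The fall was 1.98 for araG (SE 0.37, limma adjusted p = 0.00012), from 43.1 ± 10.4 to 10 ± 1.89 FPKM, and 1.90 for araH (SE 0.37). They were the 2 of 11 measured genes for uptake of other sugars that changed (2 adjusted over the list alone, median log2 change -0.10, list adjusted p = 0.96, adjusted p = 0.99 with an estimated correlation). rimI, which acetylates a ribosomal protein, fell by 1.44 (SE 0.27) and feoA, part of ferrous iron uptake, fell by 1.34 (SE 0.37, limma adjusted p = 0.0065). Lower levels also met the test for rpsU (-1.29), spr (-1.22), rpmH (-1.14), rnc (-1.10), dnaG (-1.01) and rpsT (-1.0), which encode ribosomal proteins (rpsU, rpmH, rpsT), a peptidoglycan hydrolase, RNase III and primase. Scaling ended all 6 of these calls. The 7 libraries left out ended those of spr (-0.94), rpmH (-1.03), rnc (-0.81), dnaG (-0.70) and rpsT (-0.71). That of spr also ended without SensorArray IPTG 3 (-0.96), that of rnc without SensorArray no-IPTG 2 (-0.96), and those of dnaG and rpsT without SensorArray no-IPTG 2 or 3 or SensorArray IPTG 2 or 3 (-0.85 to -0.98). The dnaG call ended as well without SensorArray no-IPTG 1 or SensorArray IPTG 4. putA, the proline-degrading enzyme, rose by 3.00 (SE 0.87, limma adjusted p = 0.0095), from 27.6 ± 31.3 to 77.5 ± 11.7 FPKM, a call lost without the 7 libraries (0.49), without SensorArray no-IPTG 2 (2.13) or without SensorArray no-IPTG 3 (2.20). ECOLIN_23100 rose (4.76), and ECOLIN_00305 (-3.52) and ECOLIN_00310 (-3.36) fell. The median log2 change of all genes was -0.27, and 103 genes changed in limma, 8 higher and 95 lower, against 24 higher and 41 lower after scaling. The count was 50 without the 7 libraries, 57 without SensorArray no-IPTG 2 and 218 without SensorArray no-IPTG 4. The feoA call ended without SensorArray no-IPTG 2 (-1.09) or the 7 libraries (-0.72).

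Among the gates, each lac gene rose with IPTG in all 10 strains (3 of 3 adjusted over the list alone in each). The log2 change of lacZ, with SE from 0.47 to 0.54, was 5.47 in PsrA, 6.99 in HlyIIR, 5.67 in BM3R1, 5.56 in AmtR, 5.35 in QacR, 6.10 in LitR, 5.94 in AmeR, 5.25 in IcaR, 4.23 in BetI and 4.73 in PhlF. The lac call held with an estimated correlation except in HlyIIR (adjusted p = 0.22 with an estimated correlation). ECOLIN_23100 rose in each gate, by 4.78 to 5.52. araG fell in every gate but HlyIIR, by 2.31 in PsrA, 1.97 in BM3R1, 2.01 in AmtR, 1.95 in QacR, 1.88 in LitR, 1.47 in AmeR, 1.71 in IcaR, 1.40 in BetI and 1.58 in PhlF on the log2 scale, whereas in HlyIIR it rose by 1.19. The araG change lost its call after scaling in AmeR (-1.35) and BetI (-1.08), and without the 7 libraries in BetI (-1.44) and PhlF (-1.63). It was also lost without AmeR no-IPTG 2 (-1.28), AmeR IPTG 4 (-1.37), PhlF no-IPTG 1 (-1.63), PhlF no-IPTG 2 (-1.45) or PhlF IPTG 4 (-1.48), and in HlyIIR without HlyIIR no-IPTG 1 (0.85), 2 (0.83) or 3 (0.85), where it was 2.23 without HlyIIR no-IPTG 4.

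In the IPTG response of IcaR, ilvM, a subunit of acetolactate synthase, rose by 3.49 (SE 0.43, limma adjusted p = 2.8e-09) and gcvT of glycine cleavage fell by 1.46 (SE 0.26, limma adjusted p = 4.9e-05). In PhlF, malE, lamB and malF of maltose uptake rose by 2.27 (SE 0.62), 2.22 (SE 0.63) and 1.30 (SE 0.42), 3 of 4 measured maltose genes (3 adjusted over the list alone, list adjusted p = 1.3e-05, adjusted p = 0.14 with an estimated correlation). All 3 calls were lost without the 7 libraries, of which PhlF no-IPTG 1 is the one in this comparison (malE 2.10, lamB 2.22, malF 1.23), and without PhlF IPTG 3 (2.02, 2.04 and 0.98). Those of lamB and malF were lost as well without PhlF no-IPTG 2 (2.27 and 1.30) or PhlF IPTG 4 (2.31 and 1.44). The maltose list was also called higher in BetI (0 changed, 1 adjusted over the list alone, adjusted p = 0.00011, adjusted p = 0.26 with an estimated correlation). So it was in BM3R1 (0 changed, 0 adjusted over the list alone, adjusted p = 0.04, adjusted p = 0.99 with an estimated correlation), a call lost after scaling, without the 7 libraries, and without BM3R1 no-IPTG 3 (adjusted p = 0.13), BM3R1 IPTG 1 (0.052) or 2 (0.51). The heat shock list was called higher in IcaR (0 changed, 0 adjusted over the list alone, median 0.34, adjusted p = 0.00024, adjusted p = 0.23 with an estimated correlation). In BetI, hscB, an iron-sulfur cluster chaperone, fell by 1.41 (SE 0.29, limma adjusted p = 0.00047), and cysN of sulfate activation fell by 1.66 (SE 0.54), a call lost after scaling (-1.41), without the 7 libraries (-1.90) and without BetI no-IPTG 1 (-1.63), BetI IPTG 3 (-1.52) or BetI IPTG 4 (-1.52). cysN in PhlF (-1.81), rimI in BM3R1 (-1.08) and aceK in LitR (-1.13) also fell. The cysN call in PhlF ended without PhlF no-IPTG 1, 2 or 4 or PhlF IPTG 3 or 4 (-1.56 to -2.06) and after scaling (-1.65). That of rimI ended without BM3R1 no-IPTG 1, 2 or 3 or BM3R1 IPTG 2, 3 or 4 (-0.93 to -1.19) and after scaling (-0.89), and that of aceK without LitR no-IPTG 1 or 2 or LitR IPTG 1 or 3 (-0.89 to -1.07). ECOLIN_07900 rose in PsrA (1.71) and LitR (1.56).

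Counts of genes changed by IPTG in limma were 27 in PsrA (9 higher, 18 lower), 15 in BM3R1 (6 and 9), 15 in AmtR (6 and 9), 13 in QacR (6 and 7), 41 in LitR (9 and 32), 20 in AmeR (6 and 14), 107 in IcaR (12 and 95), 90 in BetI (11 and 79) and 90 in PhlF (22 and 68). After scaling the numbers higher and lower were 7 and 6 in BM3R1, 17 and 26 in LitR, 9 and 10 in AmeR, 23 and 35 in IcaR, 28 and 20 in BetI and 31 and 29 in PhlF. Before scaling the median log2 change of all genes was -0.18 in WT and BM3R1, -0.15 in AmtR, -0.14 in QacR, -0.30 in IcaR and BetI and -0.19 in PhlF. The count was 41 in PsrA and 24 in PhlF without the 7 libraries. Single libraries moved the counts of AmeR (13 without AmeR IPTG 2), IcaR (58 without IcaR no-IPTG 1), BetI (45 without BetI no-IPTG 1, 182 without BetI no-IPTG 4, 235 without BetI IPTG 1, 50 without BetI IPTG 3) and PhlF (7 without PhlF no-IPTG 1, 40 without PhlF no-IPTG 2, 190 without PhlF no-IPTG 4, 139 without PhlF IPTG 1, 31 without PhlF IPTG 3, 30 without PhlF IPTG 4).

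In the HlyIIR strain 850 genes differed between the libraries with and without IPTG. Exchanging HlyIIR IPTG 3 with HlyIIR no-IPTG 4 gave 856, so the count does not separate IPTG from other differences among these cultures. Without HlyIIR no-IPTG 4, 1172 genes changed, and over these it lay 88.9% of the way to the IPTG libraries. Its lacZ was at 5.66 FPKM and theirs at 269 FPKM or more. Genes of protein synthesis fell, among them rpsJ (log2 change -3.52), rplW (-3.37), rplD (-3.30) and rpsA (-2.56). rpsA went from 208 ± 135 to 25.1 ± 1.82 FPKM (n = 4). Of 23 ribosomal protein genes 20 fell and none rose (20 adjusted over the list alone, adjusted p = 1.6e-05, adjusted p = 0.49 with an estimated correlation). trmD, a tRNA methyltransferase, fell by 2.79 (SE 0.28, limma adjusted p = 6.7e-13). Of 5 translation factors 4 fell (4 adjusted over the list alone, adjusted p = 0.033), among them prfC (-1.95). Of 5 methionine synthesis genes 4 fell (4 adjusted over the list alone, adjusted p = 0.033), among them metN (-2.25). Both lists had adjusted p = 0.46 with an estimated correlation, and the methionine call was lost without the 7 libraries (adjusted p = 0.055). All 3 purine synthesis genes fell (3 adjusted over the list alone, adjusted p = 0.045, adjusted p = 0.46 with an estimated correlation), among them guaA (-2.55) and purH (-2.45). The purine call was lost without the 7 libraries (adjusted p = 0.076), HlyIIR IPTG 2 (0.05) or HlyIIR IPTG 3 (0.061). Genes of fatty acid degradation rose, 5 of 5 (5 adjusted over the list alone, adjusted p = 0.00039, adjusted p = 0.45 with an estimated correlation), with fadE at 3.10 (SE 0.35, limma adjusted p = 7.7e-12) and fadA at 2.90. Of 11 genes for uptake of other sugars 7 rose (7 adjusted over the list alone, adjusted p = 0.00015, adjusted p = 0.45 with an estimated correlation), among them srlE (2.56) and rbsC (2.26). In limma 282 genes were higher and 568 lower, against 427 and 343 after scaling, and the median log2 change of all genes was -0.33.

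**Figure D3:**
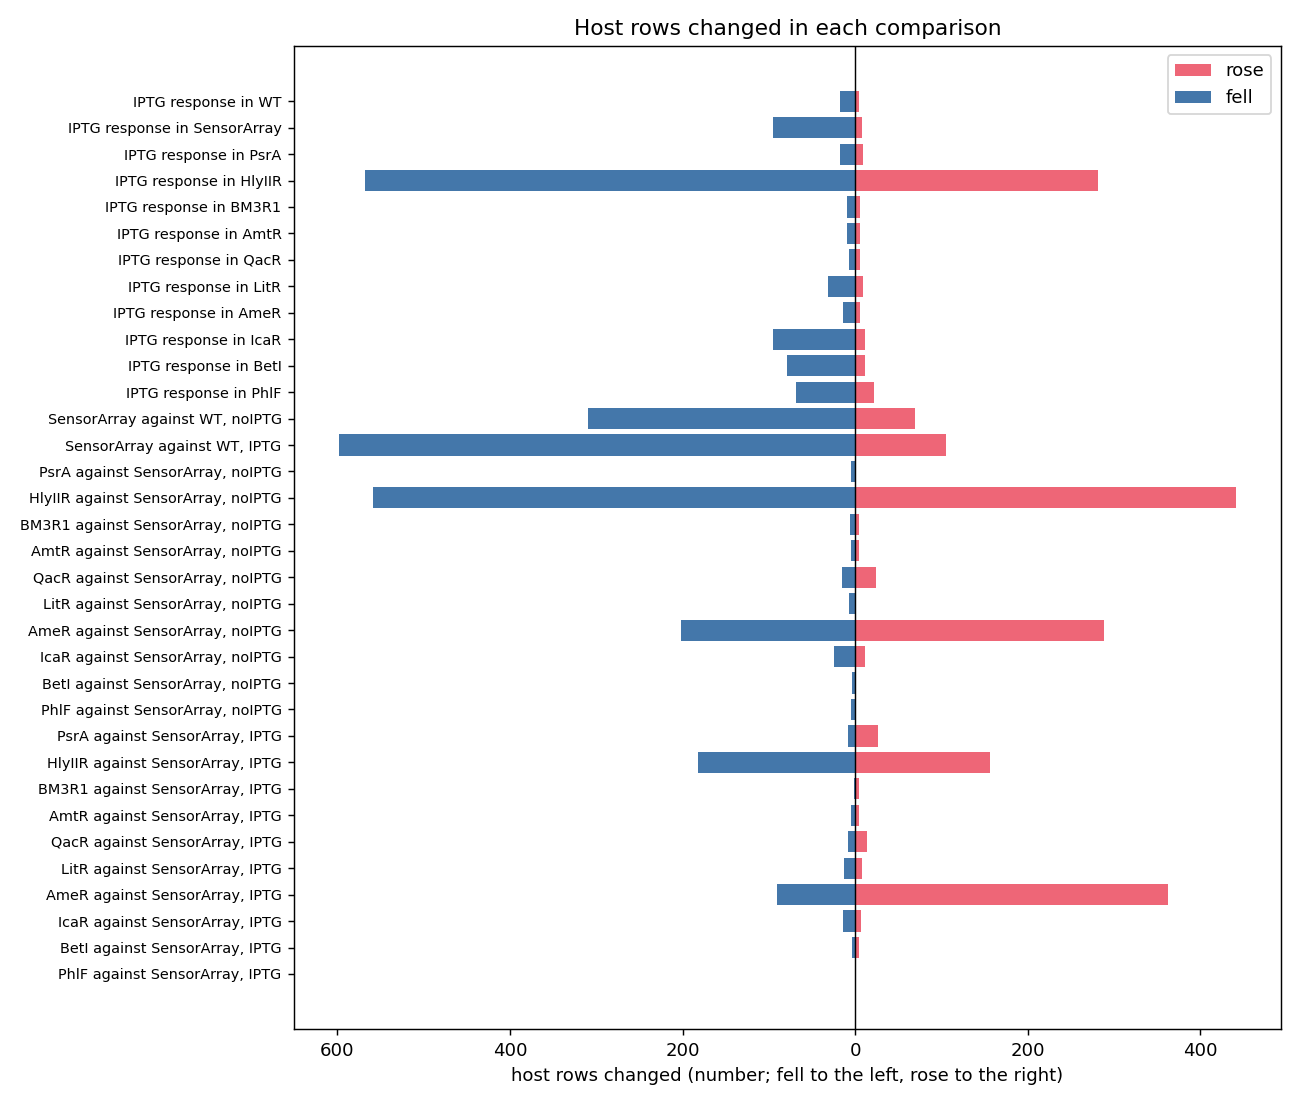
Number of host genes that rose (bars to the right) and fell (bars to the left) in each comparison except the differences of IPTG responses. The longest bar to the right belongs to HlyIIR against SensorArray without IPTG (441 rose), and the longest to the left to SensorArray against WT with IPTG (598 fell).

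SensorArray, the strain that carries the sensor regulators, was compared with WT. The strains also differed in ECOLIN_22000, ECOLIN_22005 and ECOLIN_22010, and 2 of the 4 SensorArray libraries without IPTG held these transcripts, so the comparison does not isolate the regulators. Without IPTG, hdeB, an acid stress chaperone, rose by 1.96 on the log2 scale (SE 0.13, limma adjusted p = 5e-21), from 685 ± 45 to 2690 ± 362 FPKM (n = 4). The protein-folding chaperones dnaK (1.77, SE 0.22), groEL (1.70, SE 0.22) and groES (1.66) rose, 3 of 7 heat shock genes (3 adjusted over the list alone, adjusted p = 6.3e-06, adjusted p = 0.12 with an estimated correlation). bssS (1.31) of biofilm regulation, the zinc-responsive zraP (1.29) and zntA (1.02), and araH (1.27) and araG (1.14) also rose, as did ECOLIN_19450 (4.23) and ECOLIN_08270 (3.38). The zntA call ended without SensorArray no-IPTG 1 (0.90) or 4 (0.99). The lac genes were lower, lacZ by a log2 change of -2.36 (SE 0.47, limma adjusted p = 3e-05, -4.12 without the 7 libraries), lacA of -2.43 and lacY of -2.33. uhpT, the hexose phosphate transporter, fell by 2.30 and gabD of GABA breakdown fell by 1.66 (SE 0.20, limma adjusted p = 5.1e-10). feoA (-1.63), cls (-1.53) of cardiolipin synthesis, gldA (-1.46) of glycerol oxidation and actP (-1.45) of acetate uptake also fell, with ECOLIN_07395 (-3.86) and ECOLIN_07390 (-3.77). All 6 measured flagellar genes fell, among them the flagellar sigma factor fliA (-1.46, SE 0.43, limma adjusted p = 0.0036), though only fliA and motB did after scaling (6 adjusted over the list alone, list adjusted p = 0.8). In the fit without the 7 libraries the list was called lower (adjusted p = 0.00022), with fliA at -2.25 and motB at -2.25. There lacA was at -4.11, lacY at -3.94, cls at -2.46, gldA at -2.51, actP at -2.33, ECOLIN_07395 at -6.19 and ECOLIN_07390 at -5.90. In limma 379 genes changed, 69 higher and 310 lower, against 119 and 97 after scaling, with a median log2 change of all genes of -0.39. Without the 7 libraries the count was 647, and without SensorArray no-IPTG 4 it was 243.

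With IPTG, putA was 5.73 higher on the log2 scale in SensorArray than in WT (SE 0.87, limma adjusted p = 5.2e-08), at 77.5 ± 11.7 against 0.464 ± 0.099 FPKM (n = 4). The chaperones groEL (2.95, SE 0.22), dnaK (2.71), groES (2.43) and the protease subunit hslU (1.36) rose, 4 of 7 heat shock genes (4 adjusted over the list alone, adjusted p = 5.8e-06, adjusted p = 0.12 with an estimated correlation), and hdeB rose by 2.32 (SE 0.13) from 574 to 2880 FPKM. Of 5 aromatic amino acid synthesis genes 3 rose (3 adjusted over the list alone, list adjusted p = 0.12), namely tyrA (3.13, SE 0.61), aroL (1.55) and pheA (1.37). upp (1.59) of uracil salvage and adk (1.44), adenylate kinase, rose, with ECOLIN_19450 (5.50) and ECOLIN_19295 (4.83). uhpT fell by 4.51 (SE 0.48, limma adjusted p = 2.2e-12), feoA by 2.75, gldA by 2.56, gabD by 2.42, cls by 2.38 and astD of arginine breakdown by 2.35. All 6 flagellar genes fell, among them fliD (-2.54), fliA (-2.49), fliS (-2.32) and motB (-2.26), 6 adjusted over the list alone with a list adjusted p of 0.44 (0.0029 in the fit without the 7 libraries). Of 5 fatty acid degradation genes 4 fell, fadB by 2.16, fadA by 2.01 and fadI and fadJ by 1.14 each, of which scaling ended the last pair (4 adjusted over the list alone, list adjusted p = 0.76). Of 8 genes of the TCA cycle 5 fell, among them sdhC (-1.71), sdhD (-1.39) and gltA (-1.06), and aceK rose (1.01). The aceK call ended without SensorArray IPTG 1 (0.95), SensorArray IPTG 2 (0.77), WT IPTG 2 (0.99) or WT IPTG 3 (0.97). After scaling sdhC alone of the 5 passed, and the list was not called (6 adjusted over the list alone, list adjusted p = 0.96). lacA fell by 1.49 (SE 0.49, limma adjusted p = 0.0059), the 1 changed lac gene of 3 (1 adjusted over the list alone, list adjusted p = 0.96), a call lost after scaling (-0.97). ECOLIN_07390 (-6.05) and ECOLIN_07395 (-5.95) fell. In limma 703 genes changed, 105 higher and 598 lower, against 220 and 268 after scaling, with a median log2 change of all genes of -0.47.

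Each gate was then compared with SensorArray, which lacks the gate. Without IPTG the HlyIIR strain differed most. rpsJ was 4.10 higher on the log2 scale (SE 0.45, limma adjusted p = 9.9e-13), at 319 ± 213 against 11.6 ± 6.03 FPKM (n = 4). rplW (3.96) and rplD (3.90) rose with it, as did 18 of 23 ribosomal protein genes (18 adjusted over the list alone, adjusted p = 9.9e-07, adjusted p = 0.46 with an estimated correlation). thrA of threonine synthesis rose by 4.00, the 1 changed gene of 3 in its list (1 adjusted over the list alone, list adjusted p = 0.21, adjusted p = 0.54 with an estimated correlation). Of 5 methionine genes 5 rose (5 adjusted over the list alone, adjusted p = 0.0007, adjusted p = 0.28 with an estimated correlation), with metF at 3.09 and metQ at 3.05. Of 3 branched-chain genes 3 rose (3 adjusted over the list alone, adjusted p = 0.024, adjusted p = 0.28 with an estimated correlation), with leuD at 2.95 and ilvM at 2.78. That list call was lost without HlyIIR no-IPTG 4 (adjusted p = 0.074). All 3 purine genes rose (3 adjusted over the list alone, adjusted p = 0.024, adjusted p = 0.46 with an estimated correlation), guaA by 2.98 and purH by 2.03, a list call lost without the 7 libraries (adjusted p = 0.055). Of 3 curli and fimbria genes 3 rose (3 adjusted over the list alone, adjusted p = 0.024, adjusted p = 0.28 with an estimated correlation), csgB by 2.48, csgA by 1.79 and fimA by 1.25, a list call lost without HlyIIR no-IPTG 4 (adjusted p = 0.11). astD fell by 4.14 (SE 0.37), mscL, a mechanosensitive channel, by 2.61 (SE 0.19), from 276 to 47.5 FPKM. prpB of propionate use fell by 2.87, a call lost without the 7 libraries (-0.31), SensorArray no-IPTG 2 (-2.02) or 3 (-2.02). All 5 fatty acid degradation genes fell (5 adjusted over the list alone, adjusted p = 0.024, adjusted p = 0.49 with an estimated correlation), with fadE at -3.55, a list call lost without the 7 libraries (adjusted p = 0.055). Of 11 sugar genes 8 fell (8 adjusted over the list alone, adjusted p = 0.018, adjusted p = 0.49 with an estimated correlation), among them araG (-3.44) and araH (-3.40). lacZ (-2.42, SE 0.47, limma adjusted p = 4.9e-06), lacY (-2.05) and lacA (-1.91) fell, 3 of 3 (3 adjusted over the list alone, list adjusted p = 0.25), calls lost without the 7 libraries (-0.66, -0.43 and -0.22). ECOLIN_21255 (6.05) and ECOLIN_25430 (5.33) rose, and ECOLIN_23780 (-5.63) and ECOLIN_09420 (-4.58) fell. In limma 1000 genes changed, 441 higher and 559 lower, and all 6 flagellar genes among them lost their calls without the 7 libraries.

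The AmeR strain without IPTG had higher levels of genes of DNA repair and of the TCA cycle. recA rose by 1.40 (SE 0.11, limma adjusted p = 3.4e-18), from 29.8 to 80.4 FPKM, with dinD (1.48), uvrD (1.03) and ruvA (1.01), all 4 measured SOS genes (4 adjusted over the list alone, adjusted p = 0.00071, held with an adjusted p = 0.0062 with an estimated correlation). Scaling ended the calls of uvrD and ruvA. That of ruvA also ended without SensorArray no-IPTG 1 (0.97), 2 (0.98) or 4 (0.96) or AmeR no-IPTG 1 (0.97), and that of uvrD without SensorArray no-IPTG 1. sdhA, a subunit of succinate dehydrogenase, rose by 2.39 (SE 0.27), from 54.9 ± 24.1 to 272 ± 5.26 FPKM (n = 4), with sucC (2.37) and sdhB (2.31), 5 of 8 TCA cycle genes (5 adjusted over the list alone, adjusted p = 0.00071, adjusted p = 0.28 with an estimated correlation). putA rose by 3.88 (SE 0.87), or 1.37 without the 7 libraries. Of 7 heat shock genes 4 rose (4 adjusted over the list alone, list adjusted p = 0.18) and of 6 cysteine and sulfate genes 4 rose (4 adjusted over the list alone, list adjusted p = 0.34). prpB (-2.89), glpD (-1.72) of glycerol use and all 6 flagellar genes fell, with fliD at -1.87 (6 adjusted over the list alone, list adjusted p = 0.12), and these calls were lost without the 7 libraries. The prpB call also ended without SensorArray no-IPTG 2 (-2.03) or 3 (-2.04), and that of fliD without SensorArray no-IPTG 3 (-1.23). ECOLIN_05715 rose by 6.27 (SE 0.11), from 1.26 to 174 FPKM, and ECOLIN_01845 by 3.69, while ECOLIN_24575 fell by 3.39. In limma 490 genes changed, 288 higher and 202 lower.

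In the other 8 gates without IPTG few genes were called against SensorArray. Of 2565 genes tested, 94 (BetI) to 665 (QacR) had an unadjusted p under 0.05, where chance alone gives a share of 0.05. The number in QacR lies above that share, so few calls there need not mean few differences. That in BetI lies below it. In QacR the maltose genes lamB (2.13, SE 0.55, limma adjusted p = 0.019), malE (1.82, SE 0.53), malF (1.47) and malG (1.03) rose, 4 of 4 (4 adjusted over the list alone, adjusted p = 1.5e-06, adjusted p = 0.13 with an estimated correlation), and putA rose by 2.80, 5 calls lost without the 7 libraries. All 5 calls also ended without S 2 or QacR no-IPTG 2, 3 or 4, with malF at 1.36 to 1.43 and malG at 0.96 to 1.04, S being SensorArray no-IPTG. That of putA ended without S 3 (2.00), and those of malE and malG without S 4 (1.57 and 0.90). lacA fell in QacR (-1.65, SE 0.49, limma adjusted p = 0.035), 1 of 3 lac genes (3 adjusted over the list alone, list adjusted p = 0.064). That call was lost without S 2 (-1.06), S 3 (-1.11) or QacR no-IPTG 2 (-1.63), 3 (-1.68) or 4 (-1.58), and the value was 0.04 without the 7 libraries. In IcaR, putA (2.89) and tyrA (2.51, SE 0.61, limma adjusted p = 0.013) rose and were likewise lost, and both calls ended without S 2, S 3 or IcaR no-IPTG 4. The putA call ended too after scaling (2.95) and without IcaR no-IPTG 2 (2.83) or 3 (2.89). tyrA was 1 of 5 aromatic genes that changed (2 adjusted over the list alone, adjusted p = 0.0027, adjusted p = 0.43 with an estimated correlation). ECOLIN_24575 fell in PsrA (-2.70), BM3R1 (-3.98), QacR (-3.21), LitR (-3.19), BetI (-3.01) and PhlF (-3.13), calls lost without the 7 libraries except in BM3R1. Over all gates ECOLIN_24575 fell in 10 of 10, as did ECOLIN_24470, ECOLIN_26030 and ECOLIN_26085, but each fell in 3 without the 7 libraries. Split controls gave 7, 9, 6 and 7 gates in that order, and simulated unchanged gates 0.05 or fewer on average (highest 5). ECOLIN_01420 rose in BM3R1 (3.37) and ECOLIN_11405 in AmtR (3.59). The lac and flagella lists were called lower with 0 changed genes in BM3R1 (3 and 5 adjusted over the list alone, adjusted p = 0.0074 each, adjusted p = 0.96 with an estimated correlation), AmtR (3 and 5 adjusted over the list alone, adjusted p = 0.012 and 0.0067, adjusted p = 0.78 with an estimated correlation) and LitR (3 and 5 adjusted over the list alone, adjusted p = 0.012 and 0.0049, adjusted p = 0.52 and 0.57 with an estimated correlation). In PsrA the flagella (4 adjusted over the list alone, adjusted p = 0.0099, adjusted p = 0.72 with an estimated correlation) and heat shock lists (0 adjusted over the list alone, adjusted p = 0.0029, adjusted p = 0.65 with an estimated correlation) were called lower. The maltose list was called higher there (1 adjusted over the list alone, adjusted p = 0.0029, adjusted p = 0.65 with an estimated correlation). All the lac and flagella calls were lost without the 7 libraries and without S 3 (adjusted p from 0.073 to 0.18), those of lac in AmtR and LitR without S 2 as well (0.052 and 0.053), and the heat shock call in PsrA without S 4 (0.13). The TCA list was called higher in 7 gates without the 7 libraries, against 2 with them, and the heat shock list lower in 5, against 2. These gates share 4 SensorArray libraries, and unchanged gates simulated against the same controls gave 1.02 lac and 0.93 flagella calls on average (highest 8 and 9 in 100 draws), against 3 and 4 observed.

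Counts in limma without IPTG were 5 in PsrA (0 higher, 5 lower), 11 in BM3R1 (5 and 6, or 5 and 4 after scaling), 9 in AmtR (4 and 5, or 5 and 4), 39 in QacR (24 and 15, or 30 and 11), 7 in LitR (0 and 7), 36 in IcaR (12 and 24, or 11 and 11), 4 in BetI (0 and 4) and 5 in PhlF (0 and 5). Without the 7 libraries they were 0 in limma in PsrA, BetI and PhlF, where 98, 130 and 126 genes had an unadjusted p under 0.05. They were 5 in AmtR, 1 in QacR, 2 in LitR and 4 in IcaR. With S for SensorArray no-IPTG, PsrA gave 56 without S 1 and 74 without S 4, BM3R1 39 without S 1 and 53 without S 4, AmtR 85 without S 1 and 94 without S 4, LitR 53 without S 1, 96 without S 4 and 11 without LitR no-IPTG 3, and PhlF 8 without S 4. QacR gave 107, 5, 19 and 99 without S 1, 2, 3 and 4, and 9, 11 and 5 without QacR no-IPTG 2, 3 and 4. IcaR gave 5, 9 and 113 without S 2, 3 and 4, and 62, 11 and 3 without IcaR no-IPTG 1, 3 and 4.

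In the HlyIIR strain with IPTG, glpK, glycerol kinase, was higher than in SensorArray by 5.68 (SE 0.60, limma adjusted p = 2.1e-12), from 8.37 ± 1.3 to 508 ± 188 FPKM (n = 4), and glpC (3.75), glpD (3.47) and glpA (3.00) were higher too. The curli subunits csgB (2.90) and csgA (2.82) and fimA (1.07) rose, 3 of 3 (3 adjusted over the list alone, adjusted p = 7.5e-05, held with an adjusted p = 0.0093 with an estimated correlation). The fimA call ended without HlyIIR IPTG 3 (0.89). hslU (1.70, SE 0.23), groES (1.34) and groEL (1.30) rose, 3 of 7 heat shock genes (3 adjusted over the list alone, adjusted p = 0.0012, adjusted p = 0.26 with an estimated correlation). leuD (1.95) and ilvM (1.77) rose, 2 of 3 branched-chain genes (2 adjusted over the list alone, adjusted p = 0.014, adjusted p = 0.21 with an estimated correlation), and so did 2 of 5 methionine genes (2 adjusted over the list alone, adjusted p = 0.014, adjusted p = 0.4 with an estimated correlation). Of 23 ribosomal protein genes 6 rose and 1 fell (7 adjusted over the list alone, adjusted p = 0.0094, adjusted p = 0.82 with an estimated correlation). astD (-2.18), cmk (-1.94), which phosphorylates CMP, pgi (-1.84) of glycolysis and narH (-1.05) of nitrate respiration fell. The narH call ended after scaling (-0.85) and without SensorArray IPTG 2 (-0.98), HlyIIR IPTG 2 (-0.92) or HlyIIR IPTG 3 (-0.98). In limma 338 genes changed, 156 higher and 182 lower, against 232 and 126 after scaling.

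In AmeR with IPTG, sdhB rose by 2.73 (SE 0.28, limma adjusted p = 6.8e-13), from 51.7 to 330 FPKM, with sdhD (2.64), sdhA (2.62) and sucC (2.57), 6 of 8 TCA cycle genes (6 adjusted over the list alone, adjusted p = 0.001, adjusted p = 0.35 with an estimated correlation). dinD (2.14, SE 0.18), recA (1.62) and ruvA (1.55) rose, 3 of 4 SOS genes (3 adjusted over the list alone, adjusted p = 0.00033, held with an adjusted p = 0.0023 with an estimated correlation). sufA and sufC of iron-sulfur cluster assembly fell by 1.88 (SE 0.21) and 1.35, and the outer membrane protein gene ompX fell by 1.54 (SE 0.15). lacA (1.68, SE 0.49, limma adjusted p = 0.0027) and lacY (1.55) rose, 2 of 3 lac genes (2 adjusted over the list alone, list adjusted p = 0.56). ECOLIN_05715 (6.29) and ECOLIN_05720 (3.17) rose, and ECOLIN_03890 (-2.74) and ECOLIN_16635 (-2.54) fell. In limma 453 genes changed, 363 higher and 90 lower, against 215 and 185 after scaling, with a median log2 change of all genes of 0.26.

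Among the other gates with IPTG, IcaR had ilvM 3.65 higher (SE 0.43, limma adjusted p = 3.9e-09), the 1 changed gene of 3 in the branched-chain list (1 adjusted over the list alone, adjusted p = 0.0024, adjusted p = 0.096 with an estimated correlation), and gcvT 1.43 lower (log2 change -1.43). In LitR, fecB of ferric citrate uptake fell by 1.34 (SE 0.20, limma adjusted p = 2.4e-06), the 1 changed gene of 6 for iron uptake (1 adjusted over the list alone, adjusted p = 0.013, held with an adjusted p = 0.03 with an estimated correlation), a list call lost without SensorArray IPTG 4 (adjusted p = 0.06). There folE of folate synthesis rose by 1.14 (lost without LitR IPTG 1, 0.90, or 3, 0.94), zraP by 1.00 (lost after scaling, 0.97, and without SensorArray IPTG 2 or 4 or LitR IPTG 2, 3 or 4, 0.89 to 0.99). aceK fell by 1.27 while the TCA list was called higher (median 0.79, adjusted p = 0.01, adjusted p = 0.53 with an estimated correlation), opposite in sign to its 1 changed member and lost without SensorArray IPTG 3 (adjusted p = 0.06). The aceK call ended without LitR IPTG 1 (-1.20), LitR IPTG 3 (-1.21) or SensorArray IPTG 2 (-1.04). In PsrA, mgsA of methylglyoxal synthesis (1.06), ihfA of a DNA-bending protein (1.06) and pspG of the phage shock response (1.02) rose, 3 calls lost after scaling, at 0.94, 0.91 and 0.90, and without PsrA IPTG 2 (mgsA 0.96, pspG 0.99) or PsrA IPTG 4 (ihfA 0.93, pspG 0.86). Those of mgsA (0.96) and pspG (0.99) were lost without the 7 libraries, of which PsrA IPTG 2 is one. They also ended without PsrA IPTG 3 (ihfA 0.99) or SensorArray IPTG 2 (pspG 0.99), 3 (mgsA 0.94) or 4 (pspG 0.97). In BetI, nrdI, a ribonucleotide reductase partner, rose by 1.15 (lost without SensorArray IPTG 1, 1.05, or 2, 1.05). In QacR, tyrA fell by 2.27 (SE 0.61, limma adjusted p = 0.026), 1 of 5 aromatic genes (1 adjusted over the list alone, adjusted p = 0.036, adjusted p = 0.48 with an estimated correlation). The tyrA call ended without SensorArray IPTG 1 (-2.20), 2 (-2.19) or 4 (-1.88) or QacR IPTG 1 (-2.09) or 3 (-2.15). The aromatic call there ended without SensorArray IPTG 1 (adjusted p = 0.052), 2 (0.051) or 4 (0.093), QacR IPTG 3 (0.097) or the 7 libraries (0.053). In PhlF the 1 changed gene was ECOLIN_15140 (1.05), lost without SensorArray IPTG 1 (0.97), 2 (1.01) or 4 (1.04) or PhlF IPTG 3 (0.91) or 4 (1.09). ECOLIN_01420 rose in BM3R1 (3.40), and in AmtR ECOLIN_11405 (3.53) rose and ECOLIN_23780 (-3.13) fell.

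The heat shock list was called lower than in SensorArray in 7 gates with IPTG, with 0 members changed in each, also when adjusted over the list alone. These gates share the 4 SensorArray libraries. Unchanged gates simulated against shared redrawn controls, a test added after the values were seen, gave 1.08 such calls on average and up to 8. In 1 of 100 draws there were 7 or more, and split controls gave 7. The list's median log2 change was -0.53 in PsrA (adjusted p = 0.00014, adjusted p = 0.31 with an estimated correlation). It was -0.62 in BM3R1 (0.00027 and adjusted p = 0.38 with an estimated correlation), -0.68 in AmtR (0.00014 and adjusted p = 0.31 with an estimated correlation), -0.64 in QacR (0.0026 and adjusted p = 0.34 with an estimated correlation). It was -0.59 in LitR (3.4e-08, held at adjusted p = 0.025 with an estimated correlation), -0.79 in BetI (7.8e-07 and adjusted p = 0.063 with an estimated correlation) and -0.55 in PhlF (7.7e-07 and adjusted p = 0.062 with an estimated correlation). In IcaR it was called higher (median 0.29, adjusted p = 9.7e-05, adjusted p = 0.14 with an estimated correlation). The maltose list was called higher with 0 members changed in LitR (3 adjusted over the list alone, adjusted p = 0.0026, adjusted p = 0.45 with an estimated correlation), QacR (2 adjusted over the list alone, adjusted p = 0.0026, adjusted p = 0.34 with an estimated correlation), BetI (2 adjusted over the list alone, adjusted p = 0.014, adjusted p = 0.72 with an estimated correlation), PhlF (2 adjusted over the list alone, adjusted p = 5.3e-05, adjusted p = 0.22 with an estimated correlation) and AmtR (0 adjusted over the list alone, adjusted p = 0.046, adjusted p = 0.96 with an estimated correlation). The heat shock call in PsrA was lost without the 7 libraries (adjusted p = 0.091) and without PsrA IPTG 2 (0.16), and the maltose call in BetI without BetI IPTG 3 (0.34). The maltose call in AmtR was lost after scaling, without the 7 libraries (adjusted p = 0.064), and without SensorArray IPTG 1 (0.16), 2 (0.12) or 3 (0.063) or AmtR IPTG 1 (0.38) or 3 (0.079). For the maltose list the simulation gave 1.12 such calls on average, 5 or more in 6 of 100 draws, and the split controls gave 4.

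Counts in limma with IPTG were 34 in PsrA (26 higher and 8 lower, or 14 and 18 after scaling), 6 in BM3R1 (5 and 1, or 5 and 0), 10 in AmtR (5 and 5), 22 in QacR (14 and 8), 21 in LitR (8 and 13, or 5 and 14), 21 in IcaR (7 and 14, or 9 and 8), 9 in BetI (5 and 4) and 1 in PhlF. They were 16 in BetI and 7 in PhlF without the 7 libraries. With T for SensorArray IPTG, PsrA gave 53 without PsrA IPTG 1, BM3R1 26 and AmtR 23 without T 3, and QacR 1, 3, 44 and 10 without T 1, 2, 3 and 4, 8 without QacR IPTG 1 and 1 without QacR IPTG 3. LitR gave 12, 33, 12 and 36 without LitR IPTG 1, 2, 3 and 4, and 32 without T 4. BetI gave 3, 3, 24 and 14 without T 1, 2, 3 and 4, 24 without BetI IPTG 2 and 4 without BetI IPTG 3. PhlF gave 0 in limma without T 1, T 2, T 4 or PhlF IPTG 4, with 211, 190, 305 and 215 genes at an unadjusted p under 0.05. It gave 4 without T 3 and 3 without PhlF IPTG 1.

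The difference of IPTG response between each gate and SensorArray was tested. HlyIIR differed from SensorArray at 1000 genes without IPTG and 338 with it, so its difference need not be an altered response. In HlyIIR the difference was 5.05 for glpK (SE 0.85, limma adjusted p = 1.5e-06), 4.37 for glpD, 3.90 for glcE of glycolate oxidation and 3.12 for araH, and -3.31 for rplW (SE 0.56), -3.25 for cysN and -3.08 for rplD. The lac genes also responded more, lacZ by 2.84, lacY by 2.54 and lacA by 2.49, 3 of 3 (3 adjusted over the list alone, list adjusted p = 0.11). Without the 7 libraries lacZ was at 1.08 and the calls of lacY (0.93) and lacA (0.80) were lost. Its lists differed in the direction of the HlyIIR response: ribosomal proteins (12 of 23 lower, 12 adjusted over the list alone, adjusted p = 0.00064), translation factors (4 of 5 lower, adjusted p = 0.024), methionine (5 of 5 lower, adjusted p = 0.015), purines (3 of 3 lower, adjusted p = 0.019), other sugars (8 of 11 higher, adjusted p = 0.00064) and fatty acid degradation (5 of 5 higher, adjusted p = 0.0015), with equal counts adjusted over the list alone and adjusted p = 0.46 with an estimated correlation for each. In IcaR the difference was 3.48 for ilvM (SE 0.60, limma adjusted p = 0.00049) and 3.32 for thrA (SE 0.66), and it was negative for tyrA (-3.62), pheA (-2.03) and aroL (-1.80), 3 of 5 aromatic genes (3 adjusted over the list alone, adjusted p = 0.0013, adjusted p = 0.33 with an estimated correlation), all 3 lost without the 7 libraries. nrdI (1.5) differed there as well and was lost without those libraries (1.12). All 4 calls also ended without SensorArray no-IPTG 1, 2 or 3, SensorArray IPTG 1 or IcaR IPTG 2. Counting every library, 7 of 16 such fits ended the call of tyrA (-3.23 to -3.55), 12 each those of pheA (-1.76 to -2.12) and aroL (-1.55 to -1.88), and 9 that of nrdI (1.23 to 1.51). Scaling ended those of pheA (-2.0) and aroL (-1.75). In PsrA, pspG responded 1.85 more (SE 0.30, limma adjusted p = 3.3e-05), while uhpT (2.02), fliA (1.89) and putA (-4.35) lost their calls without the 7 libraries, at 0.15, 0.53 and -0.53. All 3 were also lost without SensorArray no-IPTG 2 (1.69, 1.73 and -3.48), SensorArray no-IPTG 3 (1.65, 1.53 and -3.56) or PsrA IPTG 2 (1.21, 1.33 and -3.04). Scaling ended those of uhpT (1.84) and fliA (1.70), as did fits without PsrA no-IPTG 3 or SensorArray IPTG 1, 2 or 3. The uhpT call was lost as well without PsrA no-IPTG 2 (2.03) or 4 (2.03) or SensorArray IPTG 4 (2.15). zraP responded 1.34 more in LitR (SE 0.28, limma adjusted p = 0.0048) and pspG 1.19 more in AmeR (SE 0.30, limma adjusted p = 0.044), the second lost after scaling (1.01), without the 7 libraries (0.95) and in 10 of 16 fits without a single library (1.06 to 1.22). ECOLIN_23780 differed in AmtR (-3.14), a call lost without SensorArray IPTG 3 (-3.01), AmtR IPTG 3 (-3.11) or AmtR IPTG 4 (-3.08). ECOLIN_20520 differed in QacR (2.04) and BetI (1.36), in the second case a call lost without the 7 libraries (1.22) and in 9 of 16 fits without a single library (1.21 to 1.37).

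The number of genes whose response differed in limma was 815 in HlyIIR (423 higher, 392 lower), 110 in PsrA (92 and 18, or 33 and 34 after scaling), 18 in LitR (9 and 9, or 6 and 11), 20 in IcaR (8 and 12, or 8 and 5), 8 in AmeR (6 and 2, or 2 and 3), 4 in AmtR, 3 in QacR and 1 in BetI (or 4 and 2 after scaling). It was 0 in limma for BM3R1, where 93 genes had an unadjusted p under 0.05. It was also 0 for PhlF, where 236 did. Without the 7 libraries it was 31 in PsrA, 1 in QacR, 11 in LitR, 3 in AmeR, 13 in IcaR and 13 in BetI, where 0 of the 13 is the gene called in limma with all 92 libraries. With S and T for SensorArray without and with IPTG, PsrA gave 37, 72 and 237 without S 2, 3 and 4, 70 without PsrA no-IPTG 4 and 64 without PsrA IPTG 2. BM3R1 gave 6 without S 4 and 2 without T 1, AmtR 10 without S 4 and 0 in limma without T 3, AmtR IPTG 3 or AmtR IPTG 4 (179, 165 and 139 genes at an unadjusted p under 0.05). LitR gave 29 without S 4, and PhlF 16 without S 4. QacR gave 1, 1 and 7 without S 2, 3 and 4, and 1 without QacR no-IPTG 4 or QacR IPTG 3. AmeR gave 4, 2 and 73 without S 2, 3 and 4, 5 without T 4, 4 without AmeR no-IPTG 4, and 5 and 2 without AmeR IPTG 1 and 2. IcaR gave 7, 6, 8 and 44 without S 1, 2, 3 and 4, 9, 9 and 8 without IcaR no-IPTG 1, 3 and 4, 7, 8, 33 and 8 without T 1, 2, 3 and 4, and 9, 4 and 8 without IcaR IPTG 1, 2 and 4. BetI gave 3 without S 2, 13 without S 4, 7 without BetI no-IPTG 1, 6 without BetI IPTG 1, and 0 in limma without S 3, T 1, 2 or 4, BetI no-IPTG 2 or 4, or BetI IPTG 2 or 4, with between 206 and 387 genes at an unadjusted p under 0.05.

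Across the gates with IPTG, 746 genes differed from SensorArray in at least 1 gate and 123 in the same direction in at least 2. Unchanged gates simulated against shared redrawn controls gave 0.02 on average (0.21 and up to 12 when residuals of whole libraries were drawn). Lists drawn independently gave 47.8, and split controls 131. In at least 3 gates there were 16 genes, against 0.02 with whole residuals, 0.927 for independent lists and 16 with split controls. ilvM was among them, changed in HlyIIR (1.77), AmeR (1.38, SE 0.43) and IcaR (3.65). In at least 4 gates there were 2, ECOLIN_07960 and ECOLIN_15140 (1 with split controls). No gene changed in at least 5 of 10 gates in limma, 2 did without the 7 libraries, and 5 did without SensorArray IPTG 3.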

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

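The tests on mixed cells, on reads passed between libraries, on FPKM scaling, on the share of abundant host transcripts and on HlyIIR no-IPTG 4 were chosen after the values were seen, whereas the counts over other splits and the shift from the circuit's share of FPKM were set out beforehand.

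Single libraries lay outside the spread of their group in 10 of 52 tests of the repressor, YFP and lacZ, where chance gives about 1 in 20 groups. For lacZ these were AmeR no-IPTG 2 (9.77 FPKM, others 6.98 to 7.34), HlyIIR no-IPTG 4 (5.66, others 1.08 to 1.28), IcaR no-IPTG 2 (14, others 3.61 to 4.22), PsrA IPTG 2 (375, others 273 to 282), QacR IPTG 4 (235, others 270 to 274) and SensorArray IPTG 4 (344, others 248). For YFP they were HlyIIR IPTG 1 (10.3, others 8.64 to 8.82) and HlyIIR no-IPTG 4 (553, others 816 to 843). The repressor stood apart in IcaR no-IPTG 1 (53.9, others 12 to 16.6) and in PsrA IPTG 2 (181, others 529 to 578). The IPTG response differed from that of SensorArray for 815 genes in HlyIIR and 110 or fewer in each other gate.

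Transcripts otherwise seen in WT, in libraries of engineered strains, formed the first pattern, with a sum of 6.15 FPKM in BetI no-IPTG 1 (94.8% of the WT mean), 3.15 in SensorArray no-IPTG 2 (48.6%), 2.26 in PhlF no-IPTG 1 (34.8%), 2.14 in PsrA IPTG 2 (32.9%), 1.82 in SensorArray no-IPTG 3 (28%), 1.52 in BetI IPTG 1 (23.4%) and 1.08 in BetI no-IPTG 2 (16.6%). Reads spread evenly over the libraries of the run would reach every strain, but in 6 engineered strains the transcripts were at 0 in every library. Passage between neighbouring samples stays open. In the order of the sample numbers SensorArray and PsrA follow WT, and IcaR, BetI and PhlF come just before the next WT. The 6 strains at 0 lie between them. Whether samples were handled in that order is not given. WT cells mixed into the sample would lower every sensor regulator alike, by the WT share. In sets sorted after their values were seen, AraC*, LacI and TetR lay lower than that by over 2 SD in 5 of the 7 libraries. CinR-AM, CymR-AM, TtgR-AM and VanR-AM departed by over 2 SD in 0 of 7. That 0 depends on a WT mean pooled over IPTG levels (7.22 to 7.53 FPKM without, 4.99 to 6.48 with it): against WT of the same level BetI no-IPTG 1 departed (share 83.1%, 34.6% kept where 16.9% was due), which gives 1 of 7, while the other set stayed at 5. Sets chosen this way leave mixing open, alone or in part. An earlier test of mixing, on the best-kept regulator, gave 5 of 7 above expectation but took a maximum over 7 regulators, a poor design. Cells that lost part of the circuit stay open as an untested biological alternative.

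HlyIIR no-IPTG 4 formed the second pattern, as its host genes lay 88.9% of the way from its group to the HlyIIR IPTG libraries, where the other 3 lay at -61, -37 and -18.7%. A mislabelled sample would carry induced lacZ, but its lacZ was 2.1% of the lowest HlyIIR IPTG library. One library setting the count against SensorArray is argued against too, since 1183 genes changed without it. Whether this culture or the other 3 were unusual was not tested, and no group separates them.

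The third pattern was the excess of lower genes in SensorArray against WT. Circuit transcripts held 2.7% of FPKM with IPTG and predicted a log2 shift of -0.04, against an observed median of -0.47, which argues against their share as the cause. With the 20 most abundant host transcripts added, the share was 37% in SensorArray and 20.8% in WT and predicted a shift of -0.33, which is neither as large as the median nor under 0.5 of it, so abundant host transcripts taking much of the FPKM stay open. The authors' FPKM scaling as the cause of all calls is argued against by the 53.1% of calls with IPTG that kept their direction after median-ratio scaling. The remainder changed with scaling, so the split between higher and lower genes stays open, and a response of the host to the array remains an untested alternative.

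Other splits of the same libraries were counted for each comparison, the real one included. Among 35 splits of an IPTG response, 1 gave as many genes in WT (22, next 1), PsrA (27, next 13), BM3R1 (15, next 9), AmtR (15, next 11), QacR (13, next 3), AmeR (20, next 16) and IcaR (107, next 31). That is the fewest that 35 splits allow and lies under the set limit of 0.05. No adjustment was made over the 45 results counted this way, of which 20 lay under the limit. Chance is therefore not excluded for any single result by this test. More splits were as large in SensorArray (2 splits, 103, other 115 on exchanging IPTG 4 with no-IPTG 4), HlyIIR (2 splits, 850, other 856 on exchanging IPTG 3 with no-IPTG 4), LitR (2 splits, 41, other 84) and BetI (6 splits, 90, other 246). For PhlF the 10 splits are too few for such a test (1 split, 90, next 44). SensorArray against WT gave 1 split at each level (379, next 157, and 703, next 182), again the fewest possible.

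For gates against SensorArray without IPTG, 1 of 35 splits was as large in HlyIIR (1000, next 848), QacR (39, next 38) and AmeR (490, next 184). More splits were as large in PsrA (2 splits, 5, other 21), BM3R1 (7 splits, 11, other 93), AmtR (3 splits, 9, other 15), LitR (7 splits, 7, other 57), IcaR (4 splits, 36, other 102), BetI (13 splits, 4, other 185) and PhlF (8 splits, 5, other 167). Splits that call many times the real count point to a structure of the samples, such as the differences among SensorArray no-IPTG libraries. With IPTG, 1 split was as large in PsrA (34, next 16), HlyIIR (338, next 140), BM3R1 (6, next 5), QacR (22, next 0), LitR (21, next 13), AmeR (453, next 138) and IcaR (21, next 8), against 2 in AmtR (10, other 14), 3 in BetI (9, other 15) and 6 in PhlF (1, other 1). Of 100 regroupings of a difference of responses, 2 were as large in PsrA (110, other 137), which is under the set limit before any adjustment. The number was 8 in HlyIIR (815, other 1170), 9 in AmtR (4, other 49), 7 in QacR (3, other 125), 5 in LitR (18, other 106), 22 in AmeR (8, other 942), 7 in IcaR (20, other 135) and 36 in BetI (1, other 299), and 100 in BM3R1 (0 in limma, 93 with an unadjusted p under 0.05, other 74) and PhlF (0 in limma, 236 with an unadjusted p under 0.05, other 202). For genes changed in at least 5 gates it was 100 (0 genes in limma, other 43). Where the real count is 0, every regrouping reaches it, so these 3 comparisons test nothing. These highest counts again point to structure among the libraries.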

How the results depend on the processing

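The setting without the 7 libraries that hold transcripts of WT was added after the data were seen, and the other settings were set beforehand. The 328 results for named genes kept their call in 2018 gene and setting pairs and lost it in 277, and in 1 the sign turned: lacA in QacR against SensorArray without IPTG went from -1.65 to 0.04 without the 7 libraries. With 1 library left out the calls held in 2647 pairs and were lost in 311, and in 0 did the sign turn. Of the counts of changed genes and of called lists, 41 moved by more than 1.5 times in some setting other than leaving out 1 library. Beside counts of 0 in limma, between 41 and 465 genes had an unadjusted p under 0.05. The cause was not tested, except that a larger pseudocount shrinks low genes and fewer libraries weaken a test by construction. Depth limits the low genes most, with 1 library under 4 M reads.

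With a pseudocount of 5, 31 of 45 results moved. IPTG responses were 5 in WT, 41 in SensorArray, 453 in HlyIIR, 9 in BM3R1, 25 in LitR, 38 in IcaR, 26 in BetI and 38 in PhlF, and SensorArray against WT gave 173 without and 379 with IPTG. Gates against SensorArray without IPTG gave 653 in HlyIIR, 19 in QacR, 4 in LitR, 269 in AmeR, 18 in IcaR and 3 in PhlF. With IPTG they gave 15 in PsrA, 176 in HlyIIR, 3 in BM3R1, 9 in QacR, 10 in LitR, 239 in AmeR, 2 in BetI and 0 in PhlF in limma. Differences of responses were 58 in PsrA, 510 in HlyIIR, 3 in BM3R1, 1 in AmtR, 5 in QacR, 13 in IcaR and 1 in PhlF. With no filter, 3 results moved: 11 in BM3R1 with IPTG, and differences of 8 in IcaR and 0 in BetI in limma.

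Median-ratio scaling moved 11. IPTG responses were 9 in WT, 65 in SensorArray, 58 in IcaR and 48 in BetI, SensorArray against WT without IPTG gave 216, IcaR without IPTG 22 and BetI with IPTG 15. Differences of responses were 67 in PsrA, 5 in AmeR, 13 in IcaR and 6 in BetI. With all 96 libraries, 20 moved. IPTG responses were 12 in WT, 55 in SensorArray, 41 in BetI and 296 in PhlF. Without IPTG the gates gave 3 in PsrA, 14 in QacR, 4 in IcaR and 409 in PhlF, and with IPTG 15 in PsrA, 3 in QacR, 3 in BetI and 0 in PhlF in limma. Differences were 29 in PsrA, 1 in BM3R1, 1 in QacR, 10 in LitR, 3 in AmeR, 6 in IcaR, 0 in BetI in limma and 279 in PhlF.

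Fits of the compared groups alone moved 20. IPTG responses were 66 in SensorArray, 15 in BetI and 24 in PhlF. Without IPTG the gates gave 7 in BM3R1, 4 in AmtR, 9 in QacR and 0 in PsrA, LitR, IcaR, BetI and PhlF in limma. With IPTG they gave 46 in QacR, 1 in BetI and 0 in PhlF, and differences were 62 in PsrA, 1 in QacR, 0 in LitR, 5 in AmeR, 1 in IcaR and 0 in BetI. Without the 7 libraries, 20 moved. IPTG responses were 50 in SensorArray, 41 in PsrA and 24 in PhlF, and SensorArray against WT without IPTG gave 647. Counts for the gates are given above. Differences and genes in at least 5 gates are given above.

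Replicate numbers did not pair the samples, with 0 of 34 comparisons passing the correlation threshold of 0.1 in every pair. The replicate block moved 3 results, to 8 in PsrA and 12 in LitR without IPTG and to 15 for the difference in AmeR. Calls of gene lists went from 104 to 16 with an estimated correlation, namely 11 for the lac operon, 2 for the SOS response, and 1 each for curli and fimbriae, heat shock in LitR and iron uptake in LitR. Of the 104 list calls, 62 held in every fit without a single library and 42 did not. After scaling 11 were lost. The fit without the 7 libraries lost 28 and gained 45 others, many of them for the TCA cycle, heat shock and flagella.

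Leaving out each library in turn gave ranges for IPTG responses of 13 to 25 in WT, 57 to 218 in SensorArray, 13 to 20 in AmeR, 58 to 144 in IcaR, 45 to 235 in BetI and 7 to 190 in PhlF, and of 243 to 515 for SensorArray against WT without IPTG. Gates without IPTG ranged over 5 to 74 in PsrA, 9 to 53 in BM3R1, 8 to 94 in AmtR, 5 to 107 in QacR, 6 to 96 in LitR, 3 to 113 in IcaR and 4 to 8 in PhlF. With IPTG they ranged over 25 to 53 in PsrA, 5 to 26 in BM3R1, 9 to 23 in AmtR, 1 to 44 in QacR, 12 to 36 in LitR, 3 to 24 in BetI and 0 to 4 in PhlF. Differences of responses ranged over 37 to 237 in PsrA, 0 to 6 in BM3R1, 0 to 10 in AmtR, 1 to 7 in QacR, 13 to 29 in LitR, 2 to 73 in AmeR, 4 to 44 in IcaR, 0 to 13 in BetI and 0 to 16 in PhlF. Genes changed in at least 5 gates ranged from 0 to 5. SensorArray no-IPTG 4 gave the highest value for most results that use it.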

Other observations

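With IPTG the genes of cysteine synthesis and sulfate assimilation were called lower in BM3R1 (median log2 change -0.54, 2 of 6 adjusted over the list alone, adjusted p = 0.017), AmtR (-0.60, 2 adjusted over the list alone, adjusted p = 0.046), QacR (-0.58, 1 adjusted over the list alone, adjusted p = 0.036) and BetI (-0.60, 2 adjusted over the list alone, adjusted p = 0.015). With an estimated correlation their adjusted p was 0.73, 0.96, 0.61 and 0.72. The cysteine call was lost in the fit without the 7 libraries that hold transcripts of WT in AmtR (adjusted p = 0.061) and QacR (0.059). Without SensorArray IPTG 4 it was lost in all 4 gates (adjusted p from 0.055 to 0.12), without SensorArray IPTG 1 in AmtR (0.061) and QacR (0.052), and without SensorArray IPTG 2 in AmtR (0.053). Single gate libraries ended it as well: AmtR IPTG 3 (0.073) or 4 (0.084), QacR IPTG 2 (0.058) and BetI IPTG 2 (0.084). The 4 gates share controls. Unchanged gates simulated against shared redrawn controls gave 0.16 such calls on average and up to 8, and split controls 1. The aromatic amino acid list was called lower in BM3R1 (-0.92, 1 of 5 adjusted over the list alone, adjusted p = 0.032, adjusted p = 0.73 with an estimated correlation). The BM3R1 aromatic call ended without SensorArray IPTG 2 (adjusted p = 0.053), SensorArray IPTG 4 (0.085) or BM3R1 IPTG 3 (0.051).

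Circuit transcripts took up a share of all FPKM that differed between strains, given as values and not tested. It was 0% in WT and 2.02 ± 0.631% in SensorArray without IPTG (SD, n = 4). With IPTG it stood at 10.4 ± 3.77% in HlyIIR, against 4.03 ± 0.599% without, and at 10.2 ± 0.3% in IcaR, against 9.54 ± 0.234% without. In PsrA it stood at 2.42 ± 0.669% with IPTG and 4.72 ± 0.173% without.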
